A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

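The samples were 2 iCLIP libraries of Dbp2p from whole cells of 1 Saccharomyces cerevisiae strain that carries a tagged DBP2, described as a tagged-protein pull-down after UV irradiation. The design text of the series speaks of a biological replicate, and nothing in the labels says more about how the cultures were separated, so any spread given here is the spread between these 2 samples. The series also has RNA-seq libraries, which were not analysed here, and no untagged or input library was used here.

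The authors deposited a table per replicate with the chromosome, position, strand, base, gene and a value named normalized counts. Tested on the tables, the deposited values are a fraction of the gene's signal at each position: they lie between 0 and 1 and sum to 1, within 1e-06, in all 2787 genes of replicate 1 and all 3873 genes of replicate 2. The smallest fraction was 0.00167 in replicate 1 and 8.35e-04 in replicate 2. The normalization removed each gene's own level, so the depth of a gene, of a position and of a library is not given, and no count was inferred from the fractions. CASAVA and TopHat and the genome build sacCer3 are named in the submitters' processing notes, without versions. How repeated cDNAs were collapsed, how reads with several mapping places were treated, which flank was added to each gene and whether a minimum was set were not given in the sources used here.

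The tests had been designed before the data were examined for values that can be compared between genes. Because the fractions cannot, the number of listed positions per gene was used in place of the sum of values, and the sum, which equals the number of genes, became the alternative. The fractions served only within a gene. A number of positions depends on the expression of the gene, its length, the depth of the library and the unknown filters.

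Gene names were matched to an annotation table of assembly R64, which has the same coordinates as sacCer3. Of 4336 listed names, 4252 matched by systematic name, 81 by symbol and 1 by position (SNR20, within 5 nt of LSR1), and 2 were unmatched (46 positions in replicate 1 and 45 in replicate 2), which stayed out of all comparisons. The coordinates were checked: 58 of 58 bases listed in annotated start codons were those of ATG, 60 of 60 in stop codons were allowed there, and all 26663 matched positions lay on the strand that the systematic name gives. Of the positions under non-coding RNA names, 3941 of 3942 lay inside the annotated RNA. The annotation gave neither introns nor untranslated regions, so the reading frame of a gene here is its annotated span with any intron included, and positions outside it are described by their distance to it. Coordinates are 1-based.

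Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Each replicate was computed on its own, and a difference was called only where both replicates passed 0.05 in the same direction, after Benjamini-Hochberg adjustment over the lists or classes where there were several. Replicates were compared with Spearman's and Pearson's correlation of log2(positions + 0.5) with 100000 permutations, and listing was compared with Fisher's exact test. Gene lists and snoRNA families were compared by permutation tests of the mean log2(positions + 0.5) with 100000 resamples, 2-sided, with genes that have no position counted as 0, and list medians were set against 10000 random lists matched in 10 bins of gene length. The lists were fixed before the data were examined. Flank shares were tested by random sign changes across genes with 100000 resamples, and codon windows likewise, in genes whose reading frame is at least as long as both windows together. Intervals are 95% bootstrap intervals over genes or RNAs with 2000 resamples. Positions in both replicates were compared with 1000 circular shifts within each gene and, for protein-coding genes, its 200 nt flanks, by a 1-sided test whose smallest p is 0.001.

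The flank test was written after a first look at the data, since the design fixed only the shares, and a first form of it, the difference of signal per nt, was run and replaced after its result had been seen and is now among the alternatives. The codon windows, the base shares, the positions in both replicates and the distances to snoRNA ends and their bands, with the uniform shares set beside them, were also chosen after the data were seen. Windows of 100 nt were set as the main choice after a profile in steps of 50 nt had been seen and before the tests of either window size were run.

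The genes named in the text follow a rule fixed before the data were examined: the 20 protein-coding genes and 10 snoRNAs with the best worse rank over the replicates (ties by mean rank), the spliceosomal and other stable non-coding RNAs, DBP2, the top 3 members of each list, and the 5 features with the largest log2 ratio each way between the replicates among those above the median. The rule also asked for tRNA and ribosomal RNA names, of which none was listed, and for 5 genes of any other class, of which only FLO8 was. Of 27 genes named in the list of little expressed genes, 25 are in the annotation. Genes named outside the rule are said to be so.

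The tests of gene lists, snoRNA families, stop codon windows, the 3' flank, positions in both replicates, snoRNA distances and Pearson's r were run on simulated positions or numbers of positions in the real genes, and the other tests were not. Over 50 simulated lists of 20 genes among 6002 genes, the list test called 2% in replicate 1 and 6% in replicate 2 with no planted difference. It called 100% in each where members were drawn at 2 times their own number or 2 times the mean, whichever was larger. That also raised members without a position, so the planted difference exceeded 2-fold and the power at 2-fold was not measured. The family test over 76 snoRNAs called 2% and 0% with none planted, and 100% and 62% at 2-fold. The stop codon test called 2% (2703 genes) and 4% (3791 genes) of 50 uniform simulations and returned a mean ratio of 1.52 and 1.49 where 1.5 was planted. The snoRNA distance returned 20 and 30 nt where 20 and 30 nt were planted.

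Alternatives tried were a pseudocount of 1, leaving out positions below the 10th percentile of values, each replicate alone, the sum of values, positions per length, listed genes only, genes in either replicate, other flanks and minimum numbers of positions, leaving out genes that overlap another on the same strand, leaving out positions on another non-coding RNA gene, and counting positions within 5 nt of each other once. The closing section gives their effect.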

Results

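RNA bound by Dbp2p, a DEAD-box RNA helicase of budding yeast, was mapped by iCLIP, in which UV light joins a protein to the RNA it touches and the joined nucleotide is read from the end of the cDNA. The cells were a MATa strain that carries DBP2 with a histidine-biotin affinity tag, grown at 30 °C to an OD600 of about 1.0 in rich glucose medium and irradiated before harvest. The samples form 1 group of 2 replicates, and the question is where in the cell's RNA the protein sits. No untagged or input library was analysed here, so no position was compared with a background. For each replicate the data list nucleotide positions, the gene each belongs to and the share of that gene's signal at the position. Replicate 1 holds 8666 positions under 2787 gene names and replicate 2 holds 18088 positions under 3873 names, a ratio of 2.09. A single position carries the entire signal for 47.9% of the genes in replicate 1 and 30.0% in replicate 2. Because the shares sum to 1 in every gene, the number of listed positions is the measure of how widely a gene was crosslinked, and the number of reads behind any value is not given.

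Transcripts of the same genes were listed in both replicates more often than independent lists would give. Of 6002 annotated nuclear protein-coding genes, 2703 were listed in replicate 1, 3791 in replicate 2 and 2243 in both, against 1707 expected from independent lists (Fisher's exact test, 2-sided, odds ratio 5.52, p = 1.94e-191). Across the 2322 annotated genes listed in both, the number of positions per gene correlated with Spearman's rho = 0.41 and Pearson's r = 0.55 on the log2 scale. Over the protein-coding genes alone rho was 0.37 and r was 0.51, and over the 73 snoRNAs in both rho was 0.55 and r was 0.51. All of these correlations are across genes, which are not independent replicates. Of the 8 correlations computed over 4 sets of genes, every permutation p was at most 2e-05 after Benjamini-Hochberg adjustment, and 1e-05 is the smallest value the permutations can give. With genes listed in either replicate and absent ones at 0, rho was 0.24 and r was 0.30.

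**Figure D1:**
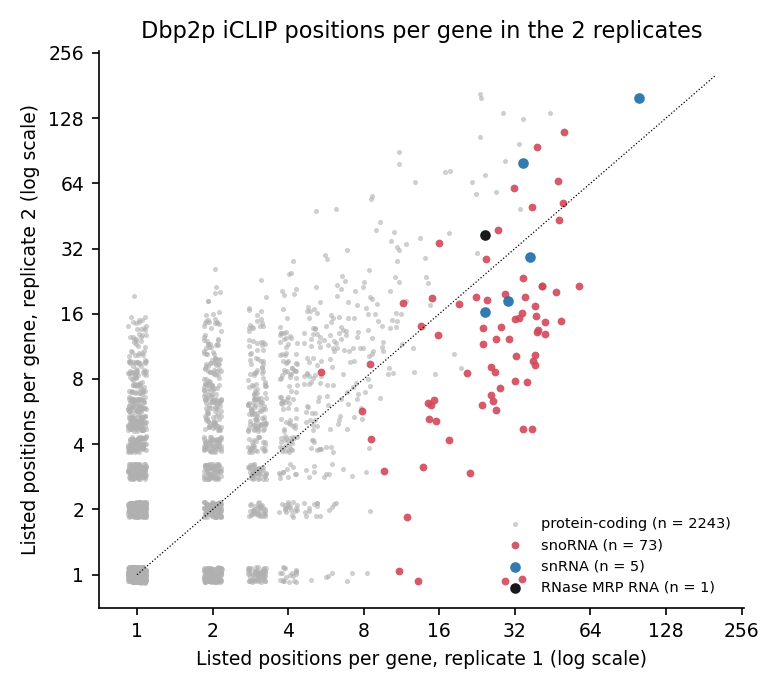
Listed positions per gene in replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale) for genes listed in both, coloured by RNA class, with a small random shift so that equal values can be seen and a dotted line of equality. Most of the 73 snoRNAs lie below the line and the bulk of the 2243 protein-coding genes lie above it.

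The listed classes of small stable RNA carried far more positions for their length than annotated protein-coding genes. The small nucleolar RNAs (snoRNAs), which guide chemical modification and processing of ribosomal RNA, had 153 positions per kilobase in replicate 1 and 91.5 in replicate 2, or 287 and 58.4 times the density inside annotated protein-coding genes. The small nuclear RNAs (snRNAs) of the spliceosome had 91.4 and 129 positions per kilobase, 171 and 82.2 times that density. Their length counts 2 times the 179 nt that the 2 annotated forms of the U5 RNA share. NME1, the RNA of RNase MRP (chromosome XIV, 585587 to 585926), had 26 and 38 positions, 143 and 71.4 times the protein-coding density. The protein-coding density spreads positions over the length of all 6002 annotated genes, of which 2703 and 3791 were listed. No RNA abundance or input was used here, so these densities are not binding per transcript. Relative to their share of annotated length, snoRNAs held 192 and 52.5 times as many positions. Protein-coding genes held 82.0% ± 12.9 (SD, n = 2) of all positions, snoRNAs 15.6% ± 12.3 (SD, n = 2), snRNAs 2.14% ± 0.598 (SD, n = 2) and NME1 0.256% ± 0.0644 (SD, n = 2). The spread between the replicates was wide for snoRNAs, which took 24.3% of positions in replicate 1 and 6.94% in replicate 2. When positions within 5 nt of each other were counted once, the mean shares were 5.37% for snoRNAs, 1.10% for snRNAs and 0.146% for NME1, and without the lowest values that of snRNAs was 1.09%.

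Nearly every snoRNA was listed. All 76 annotated snoRNAs had a position in replicate 1 and 73 of 76 in replicate 2, compared with 2703 and 3791 of the 6002 protein-coding genes (Fisher's exact test, 2-sided, adjusted p = 2.52e-26 and 5.74e-11), and this passed in both replicates. Of the 6 annotated snRNAs, 5 were listed in each replicate (Fisher's exact test, adjusted p = 0.146 and 0.636), too few RNAs for this test to tell their share from that of protein-coding genes in replicate 2. The snRNA without a position was the short form of the U5 RNA, SNR7-S (chromosome VII, 939494 to 939672). It lies inside the annotated long form SNR7-L (939459 to 939672). Of the SNR7-L positions, 46 over both replicates lay on nucleotides shared with SNR7-S and cannot be separated, so SNR7-S is not shown to be missed. The strongest SNR7-L position in replicate 1, coordinate 939492, lay outside SNR7-S. SCR1, RPR1 and TLC1, the RNAs of the signal recognition particle, RNase P and telomerase, were under no listed name in either replicate. The same held for all 5 regulatory non-coding RNAs on the list fixed beforehand and all 11 mitochondrially encoded genes. No tRNA or ribosomal RNA name was listed. The only other listed name that matches the annotation was FLO8, with 0 and 1 positions, which the annotation used here does not give as protein-coding.

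Box C/D snoRNAs, which guide methylation, and box H/ACA snoRNAs, which guide pseudouridylation, did not differ the same way in the replicates. In replicate 1 the 47 C/D members had 29.9 ± 11.6 positions (SD across RNAs) and the 29 H/ACA members 23.7 ± 12.4, a mean log2 difference of 0.35 (permutation test, 2-sided, p = 0.0264). In replicate 2 the order was opposite, with 13.9 ± 19.1 positions against 20.8 ± 19.9 and a mean log2 difference of -0.80 (permutation p = 0.0302). Detection did not separate the families by Fisher's exact test (47 of 47 against 29 of 29, p = 1.00, and 44 of 47 against 29 of 29, p = 0.283). Per 100 nt the difference was 1.43 in replicate 1 (permutation p = 1e-05) and 0.20 in replicate 2 (permutation p = 0.559). With positions within 5 nt of each other counted once, the mean difference was -0.78 and passed in both replicates. The direction of the family difference therefore rested on the measure and on the replicate.

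Among the 10 snoRNAs ranked highest in both replicates, SNR17A, the U3 RNA needed for cleavage of the ribosomal RNA precursor (chromosome XV, 780107 to 780596), had 52 and 117 positions. It shared 5 and 19 nucleotides with its copy SNR17B, where independent positions would share 1.99 and 8.02, so their assignment is uncertain. Of the SNR17A positions, 20 were at the same nucleotide in both replicates. Its strongest position was coordinate 780566 in replicate 1, with 12.6% of the signal, and 780565 in replicate 2, with 5.70%. SNR30, an H/ACA RNA that also acts in precursor cleavage (chromosome XII, 198784 to 199389), had 41 and 89 positions, with its strongest at 199375 and 199366. SNR60 (chromosome X, 349130 to 349233) had the same strongest nucleotide in both, coordinate 349160, with 12.4% and 31.5% of its signal. The other RNAs of this set were SNR190, SNR37, SNR3, SNR9, SNR48, SNR40 and SNR45, with 38 to 55 positions in replicate 1 and 20 to 63 in replicate 2. Their strongest positions differed between replicate 1 and replicate 2. They lay at nucleotides 171 and 44 in SNR190, 350 and 330 in SNR37, 178 and 68 in SNR3 and 168 and 116 in SNR9. In SNR48 they were 93 and 29, in SNR40 76 and 52 and in SNR45 134 and 35.

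Of the spliceosomal RNAs, the U2 RNA LSR1 (chromosome II, 680688 to 681862) had 99 positions in replicate 1, the most of any gene there, and 165 in replicate 2. The U1 RNA SNR19 had 33 and 82 positions, the U4 RNA SNR14 23 and 17, the U5 RNA SNR7-L 34 and 29, and the U6 RNA SNR6 32 and 17. The strongest positions of SNR14 were neighbouring nucleotides, 167458 in replicate 1 and 167457 in replicate 2, where it held 22.7% of the signal (chromosome V). In LSR1 they lay far apart, at nucleotide 48 and nucleotide 1095 of the annotated RNA.

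The snoRNA signal concentrated near the RNA's 3' end in replicate 1, and only in a narrower band in replicate 2. Positions 15 to 59 nt from the annotated end held 73.3% of the signal of an average snoRNA in replicate 1, where a uniform spread would give 34.1%, and 37.4% in replicate 2 (bootstrap 95% interval over RNAs 29.9 to 45.2), where it would give 33.8%. The replicates differed in where it lay, with 35.4% against 5.95% at 15 to 24 nt and 17.5% against 19.8% at 25 to 34 nt, where a uniform spread would give 7.59% and 7.51% in either band. The first 10 nt of the RNA held 5.54% in replicate 1 and 14.2% in replicate 2, with the same uniform shares. The last 15 nt, 0 to 14 from the end, held 3.07% and 1.63%. Within 60 nt of the end the signal-weighted median distance was 24 nt in replicate 1 (bootstrap 95% interval over RNAs 22 to 26) and 31 nt in replicate 2 (29 to 32), near the middle of that window. Within 100 nt it was 28 nt (25 to 30) and 51 nt (36 to 65).

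**Figure D2:**
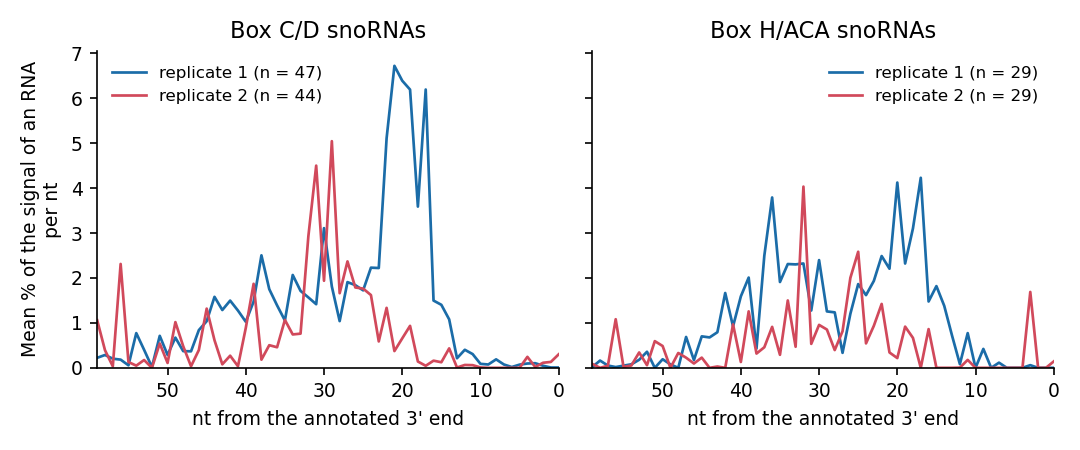
Mean share of an RNA's signal per nucleotide (y axis, %) against distance from the annotated 3' end (x axis, nt, end at the right) for box C/D (left) and box H/ACA snoRNAs (right), 1 line per replicate. The highest C/D value lies at 21 nt in replicate 1 and 29 nt in replicate 2, and the highest H/ACA value at 17 and 32 nt.

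The strongest nucleotides of the stable RNAs overlapped little at the strictest setting. The top 1% of listed positions was taken in each of 79 snoRNAs, snRNAs and NME1, rounded up, which gave 79 positions in replicate 1 and 81 in replicate 2. Of these, 2 nucleotides were shared where 0.401 were expected (Fisher's exact test, 2-sided, p = 0.0611). With the top 5% there were 8 shared against 1.16 expected (p = 2.19e-05, Fisher's exact test), while allowing 5 nt between top 1% positions gave 5 against 4.25 (p = 0.616, Fisher's exact test). The expected numbers pool the nucleotides of all RNAs, although each RNA gives its own top positions. Pooling can understate the overlap expected in short RNAs, so these p-values may be too small. Over all listed positions, 343 snoRNA positions of replicate 1 were also listed in replicate 2, against 230 after random circular shifts within each RNA, a ratio of 1.49. In snRNAs 52 were shared against 30.3, a ratio of 1.72, and in protein-coding genes with 200 nt flanks 212 against 44.8, a ratio of 4.73, which was 2.32 when 5 nt between positions were allowed. These 3 excesses passed a 1-sided permutation test over 1000 shifts (adjusted p = 0.002, 0.0032 and 0.002). Without positions on another non-coding RNA gene, protein-coding genes shared 169 against 41.9, a ratio of 4.03. NME1 shared 4 against 2.91 (permutation p = 0.348).

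Messenger RNAs of abundant housekeeping functions had more positions per gene than other protein-coding genes in both replicates. Of 10 gene lists fixed before the data were examined, 7 were higher, 1 was lower and 2 did not pass in both replicates, for the number of positions and for the share of members listed alike. The list of DEAD-box helicases shares members with translation factors (TIF1 and TIF2) and with ribosome biogenesis factors, so these calls are not separate. All 18 genes of glycolysis and fermentation were listed in both replicates, with a mean of 19.5 positions per gene in replicate 1 and 56.6 in replicate 2, or 19.7 and 22.0 times the mean of the other genes. Their mean log2 difference was 4.02 and 4.67 (permutation test, 2-sided, adjusted p = 2e-05 and 1.67e-05, the smallest the permutations can give after adjustment). The log2 differences were 2.21 and 3.06 for the 20 translation factors, 2.05 and 2.81 for the 20 cell wall and plasma membrane genes, 2.06 and 2.10 for the 138 cytoplasmic ribosomal protein genes and 1.71 and 2.34 for the 21 chaperones, with the same adjusted permutation p. Of the ribosomal protein genes 133 and 132 were listed, a share of 96.4% and 95.7%, among them RPL3, RPS31 (9 and 19 positions) and RPL2B (10 and 16). HSC82 led the chaperones after SSA2 and SSB1, with 10 and 34 positions, and SED1 followed PMA1 and CCW12 in the cell wall list, with 9 and 41. The medians of these 5 lists exceeded those of 100% of 10000 random lists matched on gene length in each replicate. Among listed genes alone all 5 still passed, with mean differences of 3.23 for glycolysis, 1.61 for translation factors, 1.40 for the cell wall, 1.11 for ribosomal proteins and 1.44 for chaperones. Some members are copies of each other and shared positions. In replicate 2, TDH2 and TDH3 shared 45 nucleotides, where independent positions would share 6.23, and ENO1 and ENO2 shared 26, where 2.24 would be shared. Such members are not independent in the tests of level and listing, and no alternative left out 1 copy of a pair.

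The remaining lists were closer to the other genes. DEAD-box helicases, 26 genes that include DBP2, were higher by 0.69 and 1.41 on the log2 scale (adjusted permutation p = 0.007 and 1.67e-05), and 19 and 24 of them were listed. Ribosome biogenesis factors, 42 genes, were higher by 0.52 and 0.71 (adjusted permutation p = 0.00791 and 0.00437), with 27 and 34 listed. The best ranked members were TIF2 (5 and 17 positions), DED1 (5 and 12) and TIF1 (5 and 10) among the helicases and RRP5 (6 and 19), NOP1 (4 and 11) and NSR1 (3 and 8) among the biogenesis factors. The strongest position of TIF2 and of TIF1 was nucleotide 253 of the gene in replicate 2, and nucleotides 478 and 1 in replicate 1. Their shared positions were not compared, so assignment between them is uncertain. Among random lists matched on gene length, the DEAD-box median stood at the 74.0th and 100th percentile and that of ribosome biogenesis at the 80.4th and 76.0th. Neither of these lists passed among listed genes alone, with mean differences of 0.37 and 0.21. The 25 genes little expressed in MATa cells on glucose, such as the galactose and sporulation genes, were lower by -0.54 and -1.08 (adjusted permutation p = 0.0344 and 9.14e-04), with 5 listed in each replicate, 20%, and a median at the 26th and 0.565th percentile of length-matched lists. STE3 had 6 and 11 positions, ADH2 4 and 10, and PHO5 1 and 5. Among listed genes alone the difference of this list turned to 0.31 and did not pass (permutation p = 0.738), so its lower level rests on how few members were listed. The 32 nuclear genes of oxidative phosphorylation did not differ (log2 differences of -0.0033 and 0.25, adjusted permutation p = 0.987 and 0.366), although the list median stood at the 49.0th and 100th percentile of length-matched lists. ATP2 had 8 and 22 positions, COR1 3 and 4, and SDH1 1 and 5. No expression data were used here, so the number of positions is not binding per transcript.

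**Figure D3:**
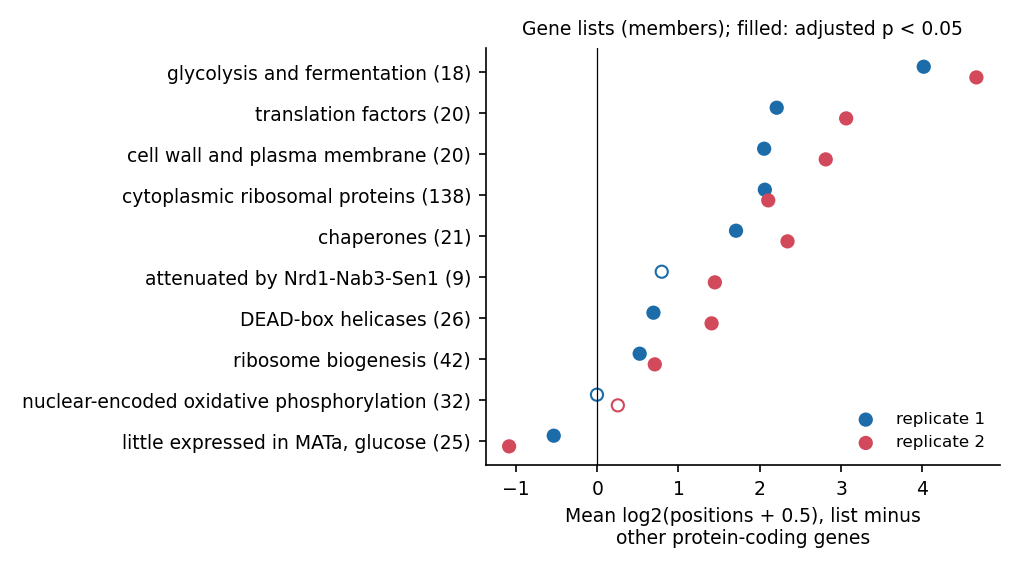
Difference in mean log2(positions + 0.5) between each gene list and the other protein-coding genes (x axis, log2), for replicate 1 and replicate 2, with the number of members in parentheses. Filled points passed the adjusted permutation test, which 7 lists did above 0 and 1 below 0 in both replicates.

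A list of 9 genes for early termination through Nrd1, Nab3 and the helicase Sen1 was examined because the study's title links Dbp2p to Sen1p. Whether each of them is shut off in this way was not tested here. The 9 genes were higher by 0.79 in replicate 1 (adjusted permutation p = 0.0612) and by 1.45 in replicate 2 (adjusted permutation p = 0.00607), so the list did not pass in both. It passed in both with a pseudocount of 1, with a mean difference of 0.86, and not per kilobase or among listed genes alone. Of its members 6 were listed in replicate 1 and 9 in replicate 2. HRP1, an mRNA cleavage factor subunit (YOL123W, chromosome XV, 87844 to 89448), had 4 and 8 positions, and 66.7% and 95.9% of its signal lay upstream of the start codon. The strongest position was at -338 nt from it in replicate 1 (coordinate 87506) and at -159 nt in replicate 2 (coordinate 87685). URA2, the first enzyme of pyrimidine synthesis, had 7 and 34 positions, and NRD1 had 2 and 5, and the strongest position of each lay inside the reading frame in both replicates.

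The protein-coding genes ranked highest in both replicates were mostly those of glycolysis and translation. PDC1, pyruvate decarboxylase (YLR044C, chromosome XII, 232390 to 234081), had 42 positions in replicate 1 and 135 in replicate 2. TDH3, glyceraldehyde-3-phosphate dehydrogenase (YGR192C, chromosome VII, 882812 to 883810), had 36 and 130, CDC19, pyruvate kinase, 29 and 127, and PGK1 25 and 98. ENO2, enolase, had 35 positions in replicate 1, of which 8 were also listed in replicate 2. PMA1, the plasma membrane proton pump, had 31 and 86 positions, and the elongation factor genes TEF2 and TEF1 had 24 and 156 and 22 and 170. The other genes of the 20 were FBA1, TDH2, EFT2, YEF3, YLR157W-E, EFT1, ADH1, SSA2, SSB1, CCW12, ENO1 and RPL3, with 12 to 35 positions in replicate 1 and 36 to 93 in replicate 2. Some are near-identical copies whose positions could not be assigned with certainty. In replicate 2, TEF1 and TEF2 shared 115 nucleotides of the reading frame and flanks, where independent positions would share 14.9, and EFT1 and EFT2 shared 50, where 2.0 would be shared. The positions of YLR157W-E lay outside its reading frame, 24 of 25 and 52 of 54 of them on the neighbouring 5S ribosomal RNA gene RDN5-4.

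**Figure D4:**
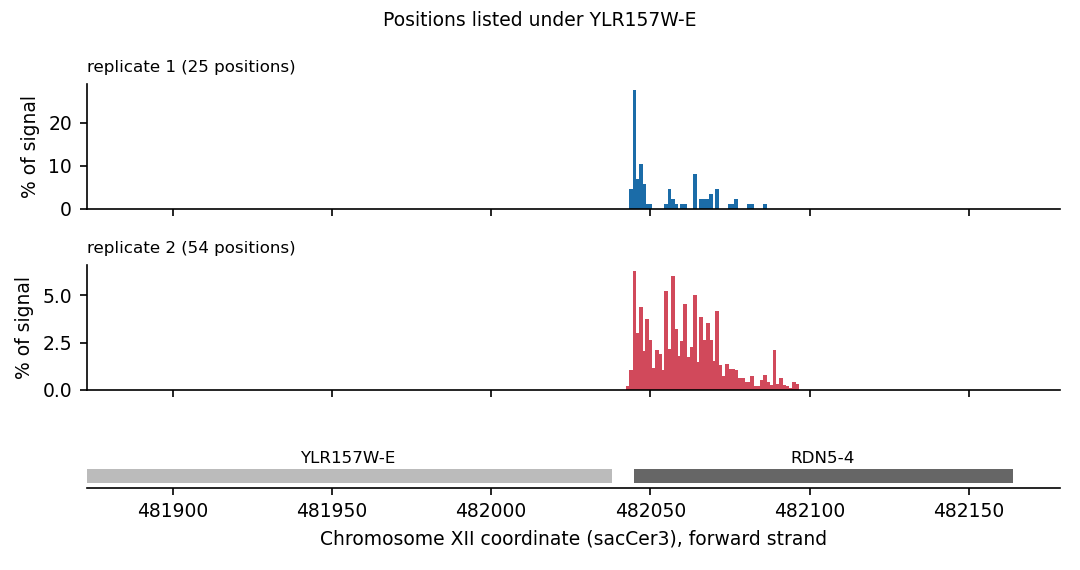
Share of signal (y axis, %) at each position listed under YLR157W-E along chromosome XII (x axis, coordinate) for replicate 1 (top) and replicate 2 (middle), with the annotated genes below. Of the 25 and 54 positions, 24 and 52 lie on RDN5-4 (482045 to 482163), and none lies inside YLR157W-E (481873 to 482037).

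DBP2 itself (YNL112W, chromosome XIV, 413639 to 416281) had 10 positions in replicate 1 and 9 in replicate 2. Coordinate 415056 was listed in both, with 10% and 5.88% of the signal. DBP2 is known to hold an intron, which the annotation used here does not mark, so positions were not split into exon and intron. In replicate 2 the strongest position was 416263 with 35.3%, close to the end of the reading frame, and 17.6% of the signal lay beyond the stop codon.

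Positions fell inside the annotated protein-coding gene for 75.3% of protein-coding positions in replicate 1 and 84.4% in replicate 2. In genes with at least 10 positions, each gene weighted equally, the 200 nt upstream of the start codon held 8.68% of the signal in replicate 1 (54 genes) and 6.25% in replicate 2 (327 genes), the reading frame 69.5% and 84.3%, and the 200 nt downstream of the stop codon 14.5% and 7.10%. A uniform spread over the reading frame and these flanks alone would put 12.1% and 10.5% in each flank, whether or not the transcript reaches that far, since untranslated regions were not annotated. The observed shares are of all signal, of which 2.67% and 0.960% lay further upstream and 4.70% and 1.34% further downstream. This lowers the differences from uniform, more so in replicate 1. A share below the uniform one is therefore not shown to be a preference of Dbp2p. The downstream share exceeded the uniform one by 2.43 percentage points in replicate 1 (permutation of signs, p = 0.370) and differed by -3.40 in replicate 2 (permutation p = 1e-04), so no call was made. With at least 3 positions per gene the differences were 3.75 points (permutation p = 5e-05) and -1.47 points (permutation p = 0.00448), again opposite. The upstream share differed from uniform by -3.39 points (permutation p = 0.180) and -4.26 points (permutation p = 3e-05), and this passed in both replicates with at least 3 positions per gene (mean -5.35 points). The first 5 and the last 5 of 10 equal bins of the reading frame held 34.1% and 35.4% in replicate 1 and 41.9% and 42.5% in replicate 2 (permutation p = 0.777 and 0.851). With at least 3 positions per gene the first part held 7.36 points more in replicate 1 (permutation p = 1.5e-04) and 2.56 more in replicate 2 (permutation p = 0.100), which did not pass in both.

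Closer to the codons, the 100 nt after the stop codon held 644 positions in replicate 1 against 328 in the 100 nt before it, a ratio of 1.96 (bootstrap 95% interval over genes 1.68 to 2.27, adjusted permutation p = 2e-05). In replicate 2 there were 1065 against 1000, a ratio of 1.07 (0.928 to 1.22, adjusted permutation p = 0.366), so the excess was not called in both. With windows of 50 nt the ratios were 2.19 and 1.29 (adjusted permutation p = 2e-05 and 0.0303). The 100 nt before the start codon held fewer positions than the 100 nt after it in both replicates, with ratios of 0.650 (0.553 to 0.772) and 0.569 (0.490 to 0.658) and an adjusted permutation p of 2e-05 each. With windows of 50 nt these were 0.902 and 0.750 (adjusted permutation p = 0.366 and 0.00709), which did not pass in both. Windows upstream of the start codon may reach beyond the transcript, so the deficit is not shown to be a preference of Dbp2p.

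**Figure D5:**
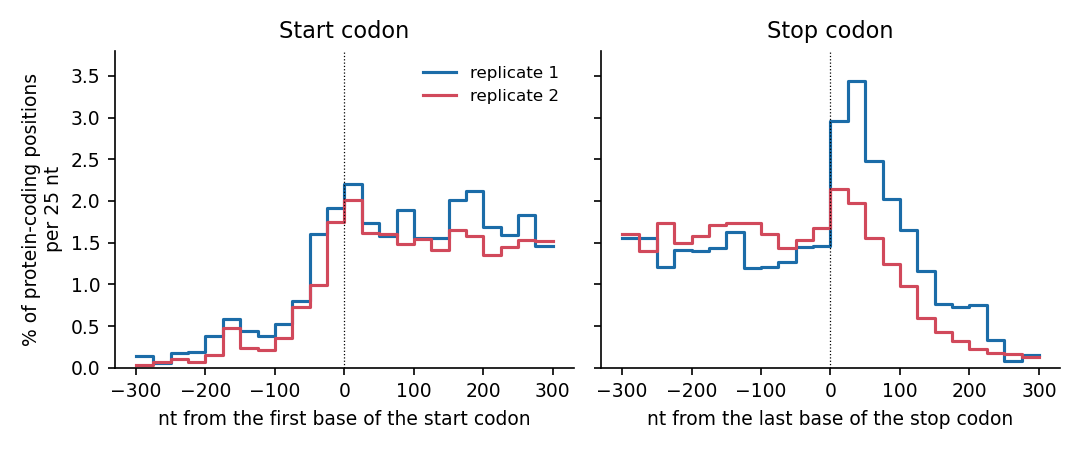
Share of protein-coding positions per 25 nt (y axis, %) around the first base of the start codon (left) and the last base of the stop codon (right), 1 line per replicate (x axis, nt). In the 25 nt directly after the stop codon the share was 2.96% in replicate 1 and 2.15% in replicate 2, compared with 1.47% and 1.67% in the 25 nt directly before it.

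The listed nucleotides were mostly A or T. A made up 45.7% of positions in replicate 1 and 39.0% in replicate 2 (mean 42.3% ± 4.79, SD, n = 2), T 33.1% and 29.7% (31.4% ± 2.35), G 12.5% and 16.4% (14.4% ± 2.80) and C 8.72% and 14.9% (11.8% ± 4.35). Downstream of protein-coding reading frames T rose to 43.7% and 38.1% of positions, compared with 28.4% and 28.3% inside them. These shares were not tested against the base content of the genes, since no genome sequence was used here.

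Between the replicates, 62 of the 76 snoRNAs had fewer positions in replicate 2, with a median log2 ratio of -1.25, while the median for protein-coding genes above the same level was 1.28. The features lowest in replicate 2 relative to replicate 1 were SNR76, with 24 positions against 0, SNR65, with 15 against 0, SNR54, with 32 against 1, SNR87, with 10 against 0, and SNR39, with 29 against 1. Those highest in replicate 2 were AMS1 (0 against 17), UTP20, RPL19B and MMF1 (0 against 16 each) and HTA1 (0 against 15). These are differences between 2 libraries of the same group and have no replicate check.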

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

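The tests of the tRNA and 5S positions were chosen after the positions had been seen.

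Under 2 names that match no gene of the annotation used here, and that entered no comparison, positions were listed above the limit of 3 counts: YOL013W-A with 22 in replicate 1 and 29 in replicate 2, and YPR108W-A with 24 and 16. No control sample was used here to set a background. Of the YOL013W-A positions, 19 and 29 lie on the tRNA gene YNCO0011W (chromosome XV, 301097 to 301198), and of the YPR108W-A positions, 23 and 15 lie on the tRNA gene YNCP0016W (chromosome XVI, 744284 to 744355), on the same strand. In YPR108W-A the strongest position was coordinate 744315 in both replicates, with 24.3% and 18.7% of the signal.

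The same pattern occurred under protein-coding names next to tRNA genes and a 5S ribosomal RNA gene: YLR157W-E (24 and 52 positions on RDN5-4), MSS1 (12 and 22), TEN1 (13 and 17), ADY4 (10 and 23) and MEF2 (9 and 8), of which all but YLR157W-E were chosen after their values were seen. With the 2 unmatched names, 110 positions in replicate 1 and 166 in replicate 2 lie on such genes, and 73 of them are at the same nucleotide in both. These 7 are all the names with any position on a tRNA or ribosomal RNA gene. A spread along a transcript of the named gene that runs through the RNA gene is argued against for the 5 protein-coding names. Of all their positions, 89.5% and 93.1% lay on the RNA gene, whose length is 5.195% of the windows. The exact 95% intervals (80.3 to 95.3% and 87.4 to 96.8%) treat positions as independent, although they cluster within 5 names. These names were picked for having a position there, which can raise the share. Over all genes with such an RNA gene in the window (11 and 18), the shares were 76.6% and 69.5%. There the RNA gene's length is 1.85% and 2.27% of the windows, and only 4 and 3 genes contributed. RNA of the tRNA and 5S genes themselves may be the source, but no test here decides it: flank positions on these genes were 93.4 and 80.6 times the number expected from their share of the flank length (49 against 0.524 and 91 against 1.13), yet nearly all come from YLR157W-E, MSS1 and TEN1, which prompted the test. Why the RNA genes' own names are absent stays open, and no biological explanation was tested.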

How the results depend on the processing

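The alternatives that count nearby positions once, leave out positions on another RNA gene, change the codon or snoRNA windows, take signal per nt or weight positions, genes or bases differently were chosen after the data were seen, as were all alternatives of the codon windows, bases, snoRNA distances and positions in both replicates. Of 300 values recomputed for 49 results, 263 kept their direction and their side of the threshold, or moved by less than the spread between replicates. Of these 300, 82 left out a replicate, and many of those could not have changed. A result called because both replicates passed also passes in either replicate alone. A share or distance averaged over the replicates always moves by less than their SD when a replicate is left out. Among the other 218 values, 190 met the same rule. Both agreement coefficients, the odds ratio of listing, the snoRNA detection and the higher level of glycolysis, translation factor, cell wall, ribosomal protein and chaperone genes kept their call under each alternative run, although rho and r were lower over genes in either replicate. The cause was not tested for any change below unless it is given.

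With the sum of values, which counts genes by construction, the class shares became 97.49% for protein-coding genes, 2.31% for snoRNAs, 0.154% for snRNAs and 0.0309% for NME1. Counting positions within 5 nt once gave 1.10% for snRNAs and 0.146% for NME1, and leaving out the lowest values gave 1.09% for snRNAs. Among listed genes only, 0 lists were lower, the differences fell to 0.21 for ribosome biogenesis and 0.37 for DEAD-box helicases, and reversed to -0.096 for oxidative phosphorylation and 0.31 for the little expressed genes (5 members left). The Nrd1-Nab3-Sen1 list passed with positions within 5 nt counted once (0.91), without overlapping genes (1.23) and with a pseudocount of 1 (0.86), but not per kilobase (1.32, p = 0.281 by permutation) or among listed genes only (0.45, p = 0.280). The family difference became -0.78 with positions within 5 nt counted once and 0.82 per 100 nt. The 3' flank difference reversed to 1.14 points with at least 3 positions per gene and 1.21 points with 100 nt flanks; the 5' flank difference passed at -5.02 points without positions on other RNA genes and at -5.35 with at least 3 positions. The difference between the first and last bins reversed to 0.638 points without overlapping genes, 2.79 with positions within 5 nt counted once and 4.96 with at least 3 positions. The overlap of the strongest positions, set against the pooled expectation, passed with the top 5% (odds ratio 7.64), while within 5 nt the odds ratio fell to 1.19. Windows of 50 nt gave mean ratios of 1.74 at the stop codon, which passed, and 0.826 at the start codon, which no longer did. The snoRNA distance was 39.5 nt with a window of 100 nt.

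With each replicate left out, the results that changed, other than class shares, base shares and snoRNA distances, ranged from 0.79 to 1.45 for the Nrd1-Nab3-Sen1 list level and from 21.7 to 36.9 percentage points for its listing, from -0.0033 to 0.25 for oxidative phosphorylation, from -0.80 to 0.35 for the snoRNA families, from -3.40 to 2.43 points for the 3' flank, from -4.26 to -3.39 points for the 5' flank and from 1.07 to 1.96 for the stop codon ratio. No paired analysis was possible because the samples form 1 group. The comparison of intron-containing with intronless genes was not run, since the annotation used here gives no introns; nor were totals without ribosomal RNA (no such name) or assignment without strand (names were already assigned). Summing signal over genes is the same as weighting genes equally when each sums to 1. The depth, which is not given, limits every absence: a gene without a position was not listed, not shown to be unbound.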

Other observations

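The tests of the replicate difference at the snoRNA ends were chosen after it had been seen, in several forms, and the genes in the next paragraph were chosen after their values were seen; the tests of the stop codon excess and of the snoRNA families were written down before they were run, on patterns already seen, but the rule for the family test was made stricter after its result had been seen.

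A few messenger RNAs carried the same short cluster of positions in both replicates downstream of the stop codon. In EDC1, an activator of mRNA decapping, 7 positions from 80625 to 80631 on chromosome VII were listed in both, all at T, with 91.7% and 68.4% of the gene's signal. In BRN1, a condensin subunit, 6 positions from 43106 to 43111 on chromosome II, all at T, held 14.8% and 71.1%. UPC2, a regulator of sterol genes, had 5 positions from 892698 to 892706 on chromosome IV (4 at T), with 57.1% and 51.6%, and ADA2, of the SAGA complex, had 4 from 1357481 to 1357488, all at T, with 20% and 28.1%. ALT2 had 5 from 678035 to 678048, all at A, with 27.5% and 75.0%. The first nucleotide of the mature RNA was listed in 36 snoRNAs in replicate 1 and 18 in replicate 2, and held 1.74% and 6.61% of the mean snoRNA signal.

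In replicate 1 positions were 1.96 times as frequent in the 100 nt after the stop codon as before it. A preference of crosslinking for T in T-rich flanks does not account for all of this: over A, C and G positions alone the ratio was 1.43 (95% interval 1.204 to 1.72), although it was 3.85 over T positions (1.47 in replicate 2, 1.22 to 1.78). A preference for A as well as T was not tested, since no base content was used. In replicate 1, A or T made up 86.0% of downstream positions and 78.9% of those in the reading frame, while A alone made up 42.3% and 50.5%. Transcripts of a gene on the same strand do not account for the excess either, since without genes that have such a gene within 200 nt downstream the ratio was 1.94 (1.67 to 2.26). In replicate 2 the corresponding ratios were 0.907 and 1.06, and windows of 50 nt gave an excess in both replicates (2.19 and 1.29), as T positions did at 100 nt. Whether Dbp2p binds near the 3' ends of messenger RNAs stays open, and no biological explanation was tested.

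The snoRNA signal at 25 to 34 nt from the 3' end minus that at 15 to 24 nt was -17.8 percentage points in replicate 1 (95% interval -23.8 to -12.0) and 13.8 in replicate 2 (7.56 to 20.3), but the bands were chosen from the peaks and each interval comes from 1 library, so binding at 1 fixed distance is neither excluded nor shown. The length of cDNA fragments that reach the RNA's 3' end may set the distance. Family medians within 60 nt differed by 4 nt in replicate 1 and 1 nt in replicate 2, which met the rule as first written, but a flat spread would also put both near the middle of the window. Within 100 nt, a check added afterwards, they differed by 3 and 24 nt with overlapping intervals (39 to 70 and 30 to 60 in replicate 2), so fragment length and binding cannot be told apart here. No biological explanation was tested.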
